A study of Mus musculus with 15 samples.

How the data were processed

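PolyA RNA from sorted skin tumour cells of mice with basal cell carcinoma was sequenced in 15 libraries. Of these 4 were labelled control, 8 were at 6 days and 3 at 14 days of vismodegib. Per the labels' protocols, cells collected in sort buffer were lysed, RNA was purified on silica columns, and its amount and integrity were read on a Bioanalyzer. Per the file headers, the deposited counts are reads that aligned uniquely to each gene, and the deposited RPKM values are the same counts divided by gene length and by a size factor for each library. Per the submitters' processing notes, the aligner was GSNAP and the genome GRCm38. Versions, the gene annotation, strand handling and the sequencing kit are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Ratios of RPKM to count were fixed for each gene up to library factors (largest relative deviation 5.0e-13), and the RPKM values were used for no test.

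The files list 36528 genes by Entrez identifier, of which 31049 matched a RefSeq gene table of GRCm38 and 5479, with 1.24 to 1.59% of the counts, did not and kept their identifier. Coordinates are from that table. Groups were taken from the treatment label, and replicate numbers were given in accession order. No 2 libraries matched within sampling noise (smallest chi-square per degree of freedom 56.76 over 105 pairs). Total counts ran from 27336935 to 256569828, and a floor of 3 counts per library equals at most 0.105 CPM. Intervals of counting error do not cover PCR duplicates, which the counts do not mark.

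Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr on group, quasi-likelihood F test) in 1 fit over all 15 libraries with no covariate, leaving 18751 genes and 12 residual degrees of freedom. The common biological coefficient of variation was 0.579. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM, and ± gives the SD between libraries. The design, the lists, the rule for named genes and most other settings were fixed before the data were examined. The 3 comparisons are 6 days against control, 14 days against control and 14 against 6 days.

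Of 28 fixed gene lists, 26 were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over all 78 list tests. They covered Hedgehog, Wnt, Notch, BMP and TGF-beta, p53, interferon, immediate early, wound, cholesterol synthesis and antigen presentation transcripts, mitosis, DNA replication, hair bulge, hair germ, basal and differentiating epidermis, upper follicle, sebocytes, other cell types and mitochondrial transcripts. The lymphoid list had 1 tested gene, and the list of sex-linked genes served to check samples. Camera with an estimated correlation kept 3 of 22 calls, Wnt at 6 days and myeloid at 14 days against control and against 6 days. List means per library were compared with two-sided exact permutation tests. Named genes were, for each comparison, the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 10 CPM and fully separated groups, leaving out gene models without an established name and sex-linked genes. To these were added up to 4 called members of each list and 24 genes fixed by name, which made 96 genes, some of which are not reported here. Genes outside this rule are named as list members or markers of other cell types.

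Identifier ranges were used as a covariate, as a split and as a reason to leave libraries out. Settings fixed beforehand were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with sample weights, 2 other filters on low counts, fits of the 2 groups compared, glmTreat against a fold of 1.5, the ranges, and each library left out in turn. Added after the data were seen were range B as a covariate, sex with range B, all range B libraries left out, offsets for GC content and transcript length (known for 86.9% of tested genes) and counts thinned to the lowest total of 27336935. A result that was not called has no direction to reverse unless the alternative calls it the other way. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

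The fits were tested on simulated data drawn from the real means and library sizes for 18751 genes, 100 of them changed 2-fold and 100 changed 4-fold. For 6 days against control edgeR recovered 18 and 69 of these, with 9 false among 96 calls, and for 14 days 9 and 51, with 2 false among 62. On the same data DESeq2 made 50 false among 173 calls for 6 days and 70 among 169 for 14 days. For limma-voom with sample weights it was 9 among 98 and 2 among 61.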

Results

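The study profiled sorted tumour cells from mice with basal cell carcinoma, a skin cancer driven by Hedgehog signalling. Groups were labelled control or vismodegib, an inhibitor of the Hedgehog transducer SMO. The mice carried an inducible Cre recombinase expressed in basal keratinocytes, conditional alleles of Ptch1 (the receptor that restrains SMO) and Trp53, and a GFP reporter at Lgr5. PolyA RNA was sequenced from 4 libraries labelled control, 8 libraries at 6 days and 3 libraries at 14 days of vismodegib. The treatment label of the controls does not say what those mice received. The genotype was the same in every group, and the labels do not give the gate used for the sort. Total counts were 35568258, 31285961, 29108107 and 95464249 in control replicates 1 to 4. In 6-day replicates 1 to 8 they were 32556991, 93183564, 33363260, 38657170, 256569828, 27336935, 240328412 and 36566305, and in 14-day replicates 1 to 3 they were 162951666, 129672615 and 119045864. Levels are given as CPM, counts scaled to library totals after TMM correction. A count of 3 in a library corresponded to at most 0.105 CPM, a floor that covers counting error only. Nothing in the labels says that the libraries of a group came from separate animals, so all p-values measure the spread between these libraries.

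The submitters' sample identifiers fell into 3 number ranges, which the labels do not call batches. Range A held controls 1, 2 and 3 and 6-day replicates 1, 3, 4, 6 and 8, range B held control 4 and 6-day replicates 2, 5 and 7, and range C held the 3 14-day libraries and no others. Total counts spanned 27336935 to 38657170 in range A, 93183564 to 256569828 in range B and 119045864 to 162951666 in range C. The first principal component (32.8% of the variance) separated range B from ranges A and C, and the second took 15.1%. Libraries of the same range correlated across genes with a median r of 0.931. For libraries of the same group in ranges A and B the median was 0.892, and for libraries of the same range in different groups it was 0.921 (genes are not independent replicates). Range and 14 days cannot be told apart, whereas the 6-day comparison was also made within ranges A and B, and those values are given for the named genes and lists called at 6 days. Xist exceeded the Y-linked Ddx3y in 2 of 4 control, 4 of 8 6-day and 3 of 3 14-day libraries.

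**Figure D1:**
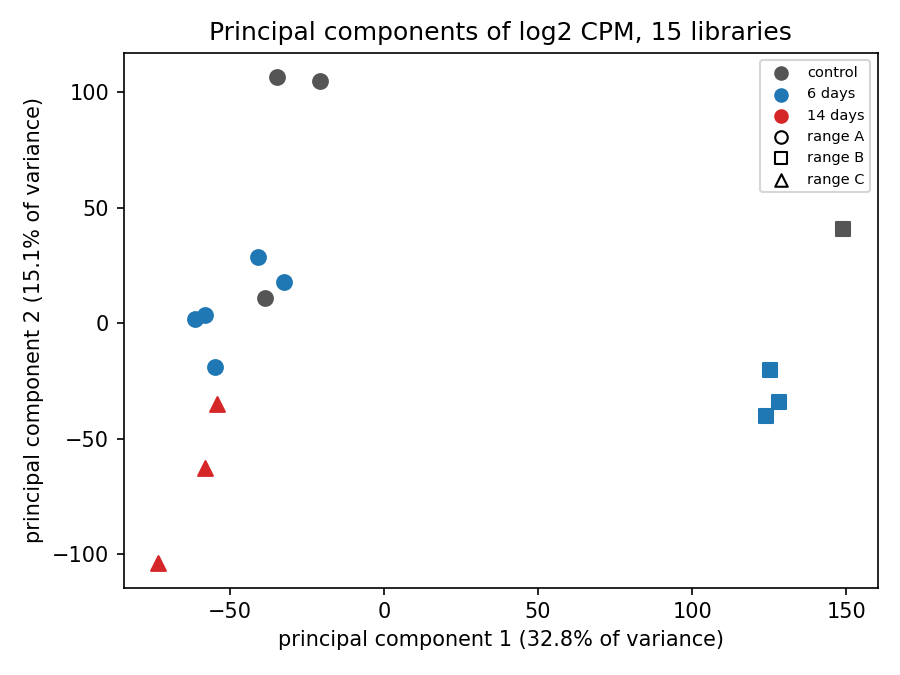
Principal components 1 and 2 of log2 CPM over the tested genes, one point per library, coloured by group and shaped by identifier range (circle A, square B, triangle C). The 4 range B libraries lie apart from the other 11 on the first component, which holds 32.8% of the variance.

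The first comparison asks what 6 days of SMO inhibition did to tumour cell transcripts. Hhip, a Hedgehog-binding decoy induced by the pathway, fell 5.54-fold, from 633 ± 492 CPM (SD, n = 4) to 114 ± 68.1 CPM (SD, n = 8). Hhip (Entrez Gene 15245, chromosome 8, 79965850 to 80058060 on GRCm38) had a log2 fold change of -2.47 (SE 0.53, adjusted p = 0.0362 by edgeR). It was -2.56 within range A and -1.64 within range B. Of the 13 measured Hedgehog readouts, Hhip alone passed over all genes, while 5 were lower and 1 higher when adjusted over the list alone. As a list they fell, with a median log2 fold change of -0.77 (camera adjusted p = 0.00023). The adjusted p = 0.296 with an estimated correlation, so that call was lost. The median was -1.07 in range A and -1.10 in range B, and the list mean lay below every control in 7 of 8 6-day libraries. Values for Ptch1 (log2 fold change -2.12, adjusted p = 0.159), Foxe1 (-3.48, 0.0589) and the transcription factor gene Gli1 (-0.78, 0.747) did not pass. In ranges A and B they were -2.62 and -2.27 for Ptch1, -3.57 and -3.49 for Foxe1 and -1.07 and -1.10 for Gli1. With the range as a covariate Ptch1 (adjusted p = 0.00987) and Foxe1 (0.0191) were called, and 5 of the 13 were lower and 1 higher. Smo itself, encoding the drug's target, stood at 274 ± 52.5 CPM in control and 221 ± 45.3 CPM at 6 days (adjusted p = 0.544). The Hhip call was lost without control 2 (3.55-fold, adjusted p = 0.162), which gave the highest value, and also without control 3 or 6-day replicate 1, 2, 3 or 5.

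**Figure D2:**
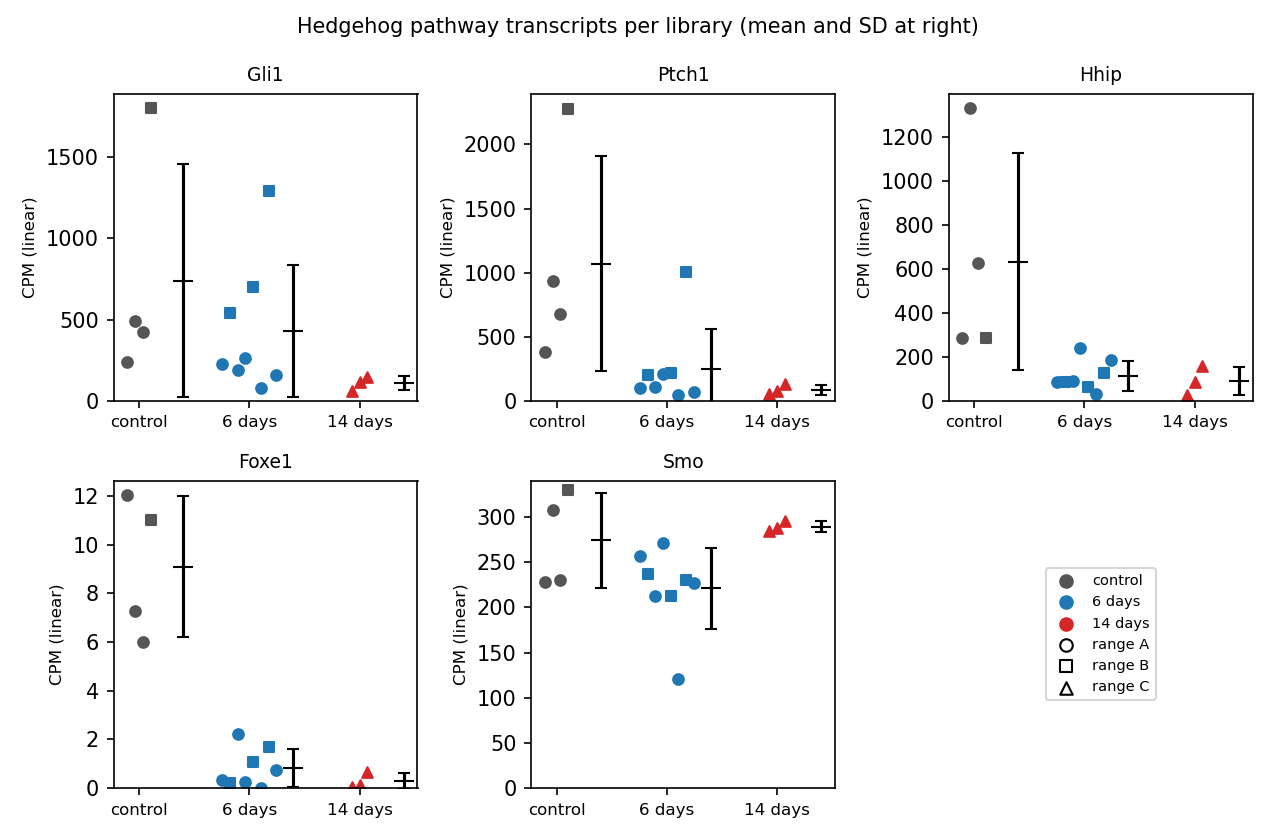
Linear CPM of Gli1, Ptch1, Hhip, Foxe1 and Smo in each library by group (circle range A, square range B, triangle range C), with the group mean and SD at the right of each group and error bars stopped at 0. Hhip averages 633 CPM in control and 114 CPM at 6 days, whereas Smo averages 274 and 221 CPM.

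Among genes whose 6-day libraries all lay above the controls, the endothelin receptor gene Ednra rose 9.09-fold (6.22 ± 5.01 to 56.6 ± 28.5 CPM). The GDNF co-receptor gene Gfra1 rose 8.60-fold, and Ccn2, a matricellular protein gene used as a readout of YAP and TGF-beta signalling, rose 7.18-fold (125 ± 35.6 to 896 ± 529 CPM). Rufy4 rose 6.54-fold, the scavenging chemokine receptor gene Ackr4 6.22-fold and the semaphorin gene Sema3d 5.97-fold. Log2 fold changes in ranges A and B were 3.38 and 2.76 for Ednra, 3.12 and 2.12 for Ccn2, 3.43 and 1.13 for Ackr4, 2.74 and 5.41 for Gfra1, 2.42 and 2.57 for Rufy4, and 2.56 and 2.90 for Sema3d. The largest fall was in Cps1, the urea cycle's carbamoyl phosphate synthetase, which fell 69.9-fold (56.4 ± 45.4 to 0.775 ± 0.720 CPM; -7.35 and -3.21 in ranges A and B). Myrip, whose product links melanosomes or secretory granules to myosin, was 26.8-fold lower, Fndc1 19.6-fold, Rap1gap2 14.2-fold, Prss35 14.0-fold and Cyp27b1, which makes active vitamin D, 11.9-fold. Edar, the ectodysplasin receptor of hair placodes, fell 9.72-fold and the Notch target Heyl 5.51-fold. In ranges A and B these falls were -4.24 and -5.55 for Myrip, -5.02 and -4.07 for Fndc1, -4.37 and -3.97 for Rap1gap2 and -4.70 and -2.48 for Prss35. They were -4.33 and -2.14 for Cyp27b1, -3.74 and -2.87 for Edar, and -1.98 and -3.27 for Heyl. Adjusted p by edgeR ran from 0.00479 for Cps1 and Cyp27b1 to 0.0451 for Heyl. Leaving out any of the 15 libraries kept the calls of Ackr4, Cps1, Cyp27b1, Fndc1 and Rap1gap2. Those of Ednra (adjusted p = 0.0926), Ccn2 (0.0502) and Edar (0.0519) were lost without control 2 alone. Gfra1 kept its call in 5 of 15, Heyl in 2, Rufy4 in 6, Myrip in 7, Sema3d in 8 and Prss35 in 9. The size of some folds rested on 1 library. Ednra was 13.9-fold higher without control 1, Cps1 46-fold lower without control 3, and Myrip (16-fold), Rap1gap2 (8.95-fold) and Heyl (3.33-fold) less reduced without control 4. Without 6-day replicate 7 the falls were 43.8-fold for Fndc1, 43.3-fold for Myrip, 22.6-fold for Rap1gap2 and 15.1-fold for Edar.

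Stem cell and lineage transcripts were less uniform at 6 days. Krt15, a keratin of hair follicle bulge stem cells, rose 3.67-fold, from 3866 ± 527 to 14180 ± 6032 CPM (adjusted p = 0.0166, 2.20 and 1.07 on the log2 scale in ranges A and B). That call was lost without control 2 or control 3 (highest adjusted p = 0.0756). It was the 1 bulge gene of 13 to pass over all genes, and 2 were higher and 1 lower when adjusted over the list alone. The bulge list rose (median 0.76, camera adjusted p = 0.0271), with adjusted p = 0.633 with an estimated correlation, and medians of 0.46 and 0.04 in ranges A and B. It was not called without control 1 (0.0601), control 4 (0.179), 6-day replicate 3 (0.0637) or replicate 8 (0.0916), nor with offsets for GC content and length (0.0806). Lgr5 averaged 545 CPM in control and 705 CPM at 6 days (adjusted p = 0.753). The mice carried a GFP reporter at Lgr5 and the sort gate is not given, so whether the sort fixed the Lgr5 level was not tested. The stem cell regulators Sox9 (log2 fold change 0.01), Lhx2 (-0.41) and Tcf7l1 (0.00) and the upper follicle markers Lgr6 (0.58), Lrig1 (0.39), Krt79 (-0.74), Gata6 (1.05) and Ly6a (-1.19) did not pass. With the range as a covariate Gata6 was called (adjusted p = 0.0443, 1.09 and 1.15 in ranges A and B). Nor did the basal keratins Krt5 (0.52) and Krt14 (0.47) or the suprabasal keratins Krt1 (1.78) and Krt10 (0.10).

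Readouts of canonical Wnt signalling rose as a list, 13 of 14 measured members having a positive log2 fold change (median 0.66, camera adjusted p = 0.000858, and adjusted p = 0.0458 with an estimated correlation). No member passed over all genes, and 1 was higher when adjusted over the list alone. The feedback gene Axin2 averaged 11.6 CPM in control and 32.6 CPM at 6 days (adjusted p = 0.318, and 0.0392 with the range as a covariate), and Lef1 (log2 fold change 1.02) had an adjusted p of 0.277. The list mean was higher in 8 of 8 6-day libraries than in every control, at an exact permutation p of 0.00202. That is the smallest value this design allows, and it became 0.109 after adjustment over all pathway and identity lists. A single list could not pass that adjustment with these numbers of libraries, so 0.109 says nothing against the Wnt rise. The medians were 0.78 in range A and 0.52 in range B.

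Cell cycle transcripts fell as lists at 6 days, with medians of opposite sign in ranges A and B. All 21 mitosis genes had negative log2 fold changes (median -1.40, camera adjusted p = 5.98e-17, and adjusted p = 0.438 with an estimated correlation). None passed over all genes, and 14 were lower when adjusted over the list alone. The median was -2.24 in range A and 0.23 in range B, and the 2 within-range effects on the list mean differed by 2.58. That difference rests on a single range B control, and its exact permutation p ran from 0.00893 to 0.134 with the common effect taken off first. The lone range B control had a list mean of 3.94, against 4.84 to 5.82 in the range A controls. The 21 DNA replication genes gave a median of -0.71 (adjusted p = 3.45e-07, and adjusted p = 0.633 with an estimated correlation), with -1.08 in range A and 0.81 in range B and none passing either way. Mki67 averaged 80.7 CPM in control and 39.1 CPM at 6 days (adjusted p = 0.691), and Top2a 109 and 46.1 CPM (0.402). Immediate early transcripts, which respond to stimulation and to tissue dissociation, rose as a list (median 0.37, camera adjusted p = 0.0381, and adjusted p = 0.633 with an estimated correlation). None of the 15 passed singly, and the medians were 0.56 in range A and 0.06 in range B. The call was lost without control 2 (0.116), control 3 (0.0739), control 4 (0.216) or 6-day replicate 3 (0.197), 4 (0.0809), 6 (0.101) or 8 (0.0589), and with offsets for GC content and length (0.105).

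Over all genes, 236 of 18751 differed at 6 days, 91 higher and 145 lower, and 67 and 122 of these by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). All 233 that could be compared had the same sign within range A and within range B, which is largely built in because they were called on these same libraries, while log2 fold changes across all 17101 genes correlated at r = 0.20 between the ranges. With the range as a covariate 844 genes were called, 343 higher and 501 lower. Within range A alone it was 468, and within range B, with its single control, 199. The 6-day effect itself differed between ranges in 10 genes. Grouping the same libraries otherwise called as many gene lists in 74 of 100 groupings at 6 days, 28 of 35 at 14 days and 34 of 100 between them, the real ones included. Groups were fully separated in 504 genes (2.69%, against 0.404% by chance), of which 201 were called. The count fell to 69 without control 2 and 91 without control 3. It was 101, 98, 110, 121 and 124 without 6-day replicates 1, 2, 3, 5 and 8, and 141 without 14-day replicate 3, which enters the shared estimate of the spread.

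The second comparison asks how tumour cells stood at 14 days of treatment. Hedgehog readouts fell, 4 of the 13 measured passing. Foxe1, a Hedgehog-responsive forkhead gene, fell 33.5-fold (9.09 ± 2.90 to 0.271 ± 0.323 CPM, n = 4 and 3) and Hhip 6.95-fold. Ptch1 (Entrez Gene 19206, chromosome 13, 63508328 to 63573460) fell 12.3-fold, from 1069 ± 838 to 87.1 ± 38.4 CPM. Ptch1 carries a conditional allele in every group, and reads from its remaining exons are counted alike. Adjusted p by edgeR was 0.0360 for Foxe1, 0.0394 for Hhip and 0.0454 for Ptch1. Gli1 averaged 738 CPM in control and 108 CPM at 14 days (log2 fold change -2.78, adjusted p = 0.0848, but -1.84 and 0.0108 with range B as a covariate), Smo 274 and 290 CPM (0.876), and Trp53 131 and 95.0 CPM (0.158). The list fell, with a median of -1.37 (camera adjusted p = 0.0028, and adjusted p = 0.389 with an estimated correlation), and 7 were lower and 1 higher when adjusted over the list alone. The call was kept in 4 of 15 left-out fits for Ptch1, 8 for Hhip and 11 for Foxe1. Without control 2, control 3, 14-day replicate 1 or 14-day replicate 2 none of these 3 was called (highest adjusted p = 0.182 for Ptch1, 0.159 for Hhip and 0.140 for Foxe1). Ptch1 was 7.67-fold lower without control 4 and Hhip 4.38-fold without control 2. Without 14-day replicate 3 Hhip was 11-fold and Foxe1 103-fold lower.

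The largest rises at 14 days among separated, well expressed genes were in Pla2g4f, a cytosolic phospholipase gene (69.9-fold), Gdpd2 (54.4-fold), Sema3d (34.4-fold), the alarmin Il33 (31-fold), the matrix protein gene Aspn (30.4-fold) and Fcgbp (28.5-fold). Spread was wide, as Pla2g4f averaged 44.5 ± 57.5 CPM and Fcgbp 1732 ± 2038 CPM at 14 days. In 14-day replicate 2 Gdpd2 (2.608 CPM) and Pla2g4f (1.343 CPM) lay barely above the highest control (2.548 and 0.9998 CPM). Its values stood further above the highest control for Il33 (9.414 against 3.117 CPM), Fcgbp (308.6 against 159 CPM), Sema3d (17.14 against 2.602 CPM) and Aspn (213.7 against 6.18 CPM). Sema3d had the smallest adjusted p of the 6 (0.0017, from 1.28 ± 0.905 to 44.1 ± 33.1 CPM). The largest falls were in Myrip (51.3 ± 45.4 to 0.0745 ± 0.110 CPM, log2 fold change -9.44, adjusted p = 0.00989), the collagen gene Col27a1 (75.7-fold lower), the ciliary neurotrophic factor receptor gene Cntfr (67.2-fold), Cps1 (54.9-fold), the potassium channel gene Kcnj8 (52.9-fold) and the proteoglycan gene Vcan (39.2-fold). Several 6-day changes also passed at 14 days. Ednra was 11.6-fold higher, Gfra1 16.9-fold, Ackr4 6.00-fold and Ccn2 5.71-fold, whereas Cyp27b1 was 24.1-fold lower, Rap1gap2 35.3-fold, Edar 17.5-fold and Heyl 19.1-fold. Rufy4 did not pass at 14 days (log2 fold change 1.85, adjusted p = 0.0954), but was called with range B as a covariate (2.37, 0.00211). The calls of Aspn, Sema3d, Fcgbp, Ednra, Gfra1, Ackr4 and Cyp27b1 were kept whichever library was left out. Fitting the 2 groups alone, however, ended the calls of Fcgbp (edgeR adjusted p = 0.0677) and Ednra (0.0594). Without 14-day replicate 1, those of Pla2g4f (0.0542), Gdpd2 (0.104), Il33 (0.0503) and Myrip (0.0531) were lost, Gdpd2 being lost also without control 2. Among the falls Vcan kept its call in 3 of 15 fits and Kcnj8 in 8. Col27a1 (highest adjusted p = 0.0865), Cntfr (0.111), Cps1 (0.072) and Edar (0.0661) were each lost without any 1 of the 3 14-day libraries, Heyl (0.0656) and Rap1gap2 (0.0669) without replicate 1 or 2, and Ccn2 (0.0589) without replicate 3. Without 14-day replicate 1 the rises were 18.7-fold for Pla2g4f, 18.4-fold for Gdpd2, 20.2-fold for Sema3d, 17.8-fold for Il33 and 9.37-fold for Fcgbp, and without replicate 2 they were 19.1-fold for Aspn and 7.23-fold for Ednra. Without control 1 they were 62.3-fold for Fcgbp, 53.5-fold for Il33, 52.6-fold for Sema3d and 17.9-fold for Ednra. The falls were 45.4-fold for Col27a1, 28.3-fold for Cntfr, 22.3-fold for Rap1gap2 and 11.5-fold for Heyl without control 4, and 34.7-fold for Cps1 without control 3. They were 156-fold for Vcan without 14-day replicate 2, and 118-fold for Kcnj8 and 40.3-fold for Cyp27b1 without replicate 3. The log2 fold change of Myrip was -8.69 without control 4. Without 14-day replicate 3 the other 2 libraries held 3 counts of Myrip, 4700-fold under the control mean (95% counting interval 1610-fold to 22800-fold).

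Basal layer transcripts rose at 14 days, 3 of 12 passing and 6 when adjusted over the list alone (median 0.60, camera adjusted p = 0.00479, and adjusted p = 0.433 with an estimated correlation). The hemidesmosome collagen gene Col17a1 rose 2.98-fold (1562 ± 457 to 4646 ± 326 CPM), the laminin gene Lamb3 1.96-fold and the integrin gene Itga6 1.94-fold (323 ± 40.0 to 626 ± 106 CPM, adjusted p = 0.0050). Itga6 kept its call in 15 of 15 left-out fits, Col17a1 in 12 and Lamb3 in 6. Fitting the 2 groups alone ended the calls of Itga6 (edgeR adjusted p = 0.0551) and Lamb3 (0.06). Differentiation transcripts rose as a list (median 1.59, camera adjusted p = 0.00331, and adjusted p = 0.633 with an estimated correlation), with 1 of 20 passing over all genes and 0 when adjusted over the list alone. That member was the suprabasal keratin Krt10, 5.85-fold higher at 239 ± 139 and 1398 ± 1460 CPM (adjusted p = 0.0452). In 14-day replicate 2 Krt10 was at 167 CPM, within the controls (163 to 447 CPM). The differentiation list mean of that library (4.02) also lay within the controls (2.99 to 5.82). The list was not called without 14-day replicate 1 (0.180), and Krt10 kept its call in 4 of 15 fits, its fold being 2.5 without that library (adjusted p = 0.344). Krt1 averaged 42.1 and 1159 CPM without passing (0.0882). Upper follicle transcripts rose as a list (median 0.53, camera adjusted p = 0.0381, and adjusted p = 0.633 with an estimated correlation), 1 of 12 passing. This was Gata6, a transcription factor gene of the upper follicle, 2.59-fold higher (adjusted p = 0.0344, kept in 9 of 15 fits). The list mean lay above every control in 0 of 3 14-day libraries. The list was not called without control 2 (0.0781), control 4 (0.216) or 14-day replicate 3 (0.0778), nor with range B as a covariate (0.116) or its libraries left out (0.182). Mitochondrially encoded transcripts, a sign of RNA and cell state, moved the other way over the same libraries. All 9 were negative (median -1.93, adjusted p = 0.00601, and adjusted p = 0.633 with an estimated correlation), with none passing singly, and the call was lost without control 4 (0.0633) and with range B as a covariate (0.0592). ATP6, COX2 and COX3 were scarcely counted, at 0.871, 1.12 and 0.54 CPM in control, where CYTB averaged 4930 CPM. Their log2 fold changes were -2.43, -3.32 and -1.99, and those of the other members ran from -1.09 to -2.17.

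Bulge and germ genes moved in both directions at 14 days. Krt15 was 3.07-fold higher (11850 ± 2407 CPM, adjusted p = 0.0223), and Nfatc1, a quiescence regulator of bulge stem cells, 3.26-fold higher. Tbx1 fell 4.78-fold (355 ± 70.0 to 74.2 ± 37.1 CPM, adjusted p = 0.00939), and the germ list's Sox4 fell 3.71-fold. The bulge list had a median of 0.19 (camera adjusted p = 0.880). Rnf43, a Wnt feedback ubiquitin ligase gene, rose 2.76-fold (from 32.2 ± 6.16 CPM, adjusted p = 0.0038) and Tnfrsf19 9.96-fold. The Wnt list did not pass (median 0.41, adjusted p = 0.0608), with 2 of 14 passing and 4 when adjusted over the list alone. Lhx2 averaged 924 and 306 CPM (0.0717), Sox9 902 and 870 CPM (0.959), and Lgr5 (545 and 703 CPM), Lgr6, Lrig1, Krt79, Ly6a, Tcf7l1, Axin2, Lef1, Krt5 and Krt14 did not pass (0.107 to 0.916). The limit set on Lgr5 by its reporter and the unknown gate holds here too. With range B as a covariate Axin2 (log2 fold change 1.67 in place of 0.76, adjusted p = 0.0195) and Lrig1 (0.63, 0.0439) were called. Tbx1 and Rnf43 kept their calls in 15 of 15 fits, Krt15, Nfatc1 and Sox4 in 11 and Tnfrsf19 in 5. Offsets for GC content and length ended the Nfatc1 call (0.139). Tnfrsf19 was 20.5-fold higher without control 1 and 4.15-fold higher without 14-day replicate 1 (0.285). In 14-day replicate 2 Tnfrsf19 was at 38.8 CPM, under control 1 (44.0 CPM).

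**Figure D3:**
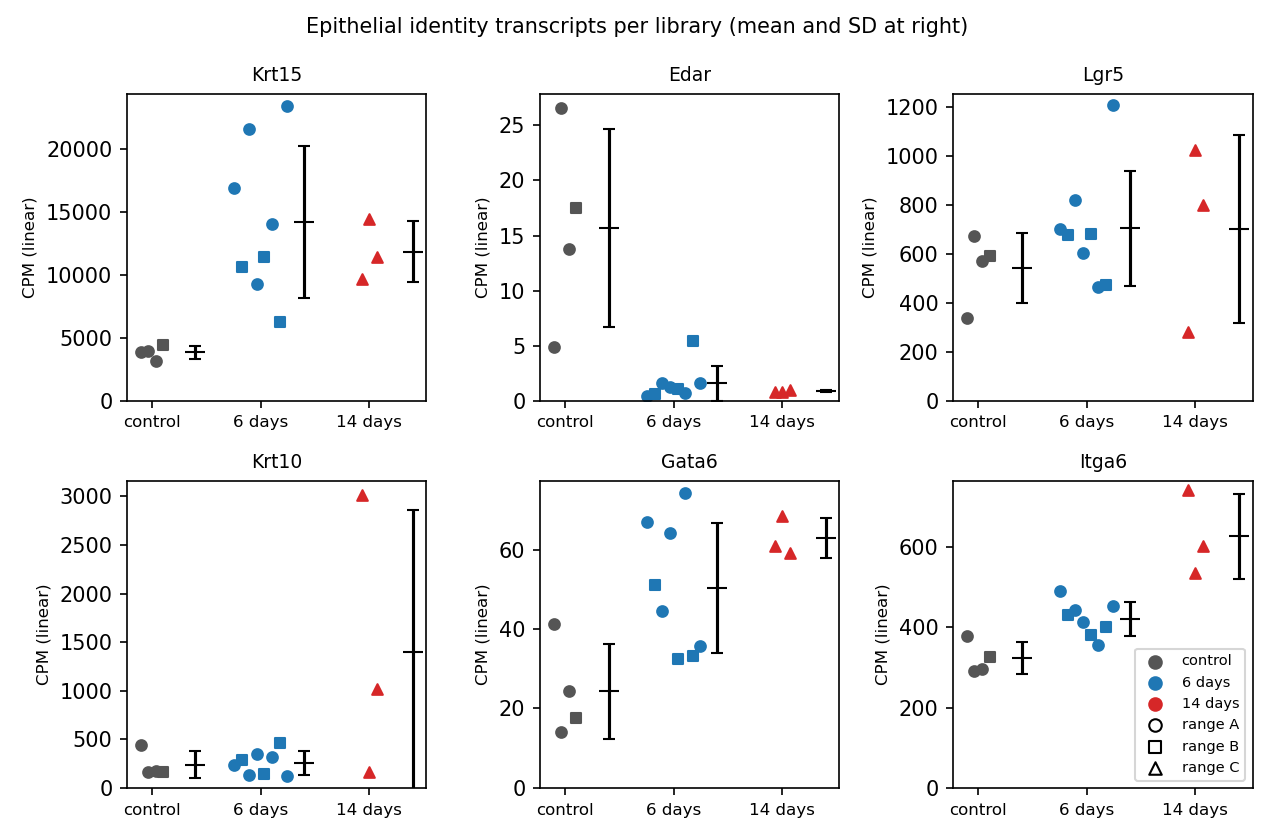
Linear CPM of Krt15, Edar, Lgr5, Krt10, Gata6 and Itga6 in each library by group (circle range A, square range B, triangle range C), with the group mean and SD at the right of each group and error bars stopped at 0. Krt15 averages 3866 CPM in control, 14180 CPM at 6 days and 11850 CPM at 14 days, and Edar averages 15.7, 1.60 and 0.893 CPM.

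Interferon and antigen presentation transcripts rose as lists at 14 days. For each, the list mean lay above every control in 1 of 3 14-day libraries. The transcription factor genes Irf1 (2.26-fold, log2 fold change 1.17, SE 0.29) and Stat2 (1.77-fold) were among the 3 of 18 interferon genes that passed, over all genes and when adjusted over the list alone. The list median was 0.58 (camera adjusted p = 0.0271, and adjusted p = 0.672 with an estimated correlation), and the call was lost without 14-day replicate 1 (0.213) or control 4 (0.399). It was also lost with range B as a covariate (0.0786) and without the range B libraries (0.343). Tapbp (2.50-fold, adjusted p = 0.0112), Tap1 and Tap2 (1.81-fold each), which load peptides on MHC class I, were the 3 of 14 antigen presentation genes to pass, with 6 when adjusted over the list alone (median 0.76, camera adjusted p = 0.000283, and adjusted p = 0.633 with an estimated correlation). Myeloid transcripts rose in the same libraries, with a list median of 2.87 (camera adjusted p = 2.69e-05, and adjusted p = 0.0458 with an estimated correlation), 4 of 12 passing and 5 when adjusted over the list alone. Levels stayed low, C1qb lying at 5.37 to 8.68 CPM and C1qc at 3.66 to 6.01 CPM at 14 days, against at most 0.166 and 0.469 CPM elsewhere. Itgam (1.64 to 2.80 CPM) and Adgre1 (0.761 to 0.917 CPM) also passed. Stat2 kept its call in 9 of 15 fits, Irf1 in 11, Tapbp in 14, Tap2 in 13, Tap1 in 4, Itgam in 15, Adgre1 and C1qb in 11 and C1qc in 4. The Tap1 call was also lost with RLE factors (0.0542) and with offsets for GC content and length (0.0751).

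At 14 days 1238 of 18751 genes differed from control, 609 higher and 629 lower, and 378 and 506 of these by at least 2-fold (edgeR, Benjamini-Hochberg adjusted). Groups were fully separated in 4394 genes (23.4%, against 5.71% by chance), 1204 of them called. No control lies in range C, so the comparison has no within-range value, and it also sets 3 libraries with Xist above Ddx3y against 2 of 4. With range B as a covariate, which takes range C to be like range A, 3196 genes were called, including all 1238. The count was 797 without control 2 and 634 without control 3, and 376, 565 and 466 without 14-day replicates 1, 2 and 3. Of the 57 calls of named genes at 14 days, 41, 29 and 33 were lost without 14-day replicates 1, 2 and 3, 25, 26 and 16 without controls 2, 3 and 4, and 3 to 10 without any other single library. Fitting the 2 groups alone ended 26 of the 57.

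The third comparison sets 14 days against 6 days, which is also the test of whether the 2 effects against control differ. Proliferation transcripts were higher at 14 days. The mitotic cyclin gene Ccnb1 was 8.15-fold higher (2.25 ± 1.24 to 18.4 ± 16.0 CPM, n = 8 and 3), the mitotic kinase gene Nek2 7.41-fold, Melk 6.13-fold, the spindle checkpoint gene Bub1b 5.99-fold, the cytokinesis gene Anln 5.82-fold, Aurkb 5.46-fold and Cdc20 4.48-fold. Of 21 mitosis genes 6 passed and 20 when adjusted over the list alone (median 1.86, camera adjusted p = 1.97e-16, and adjusted p = 0.441 with an estimated correlation). Among 21 DNA replication genes 4 passed, the helicase genes Mcm2 (2.98-fold) and Mcm4 (2.33-fold), Dtl (4.78-fold) and Chaf1a (2.55-fold), and 13 when adjusted over the list alone. That list had a median of 1.07 (camera adjusted p = 3.1e-09, and adjusted p = 0.633 with an estimated correlation). Neither list passed at 14 days against control (0.281 and 0.229). List means for mitosis at 14 days were 6.44, 4.25 and 5.32 in replicates 1 to 3, and 2 of these 3 lay above all 6-day libraries (1.74 to 4.63). None of these gene calls held without 14-day replicate 1 or replicate 3, the highest adjusted p being 0.248 for Ccnb1, 0.247 for Nek2, 0.313 for Melk, 0.361 for Bub1b, 0.385 for Anln and 0.466 for Mcm2. Ccnb1, Nek2, Melk and Bub1b kept their calls in 13 of 15 fits and Anln in 11. Chaf1a kept its call in 7, Aurkb, Cdc20 and Dtl in 5, Mcm4 in 4 and Mcm2 in 3. Without 14-day replicate 1 the folds were 4.19 for Ccnb1 and Nek2, 3.86 for Melk, 3.09 for Bub1b, 3.35 for Anln, 3.36 for Aurkb, 2.6 for Cdc20 and 3.1 for Dtl. With range B as a covariate Mcm2 (0.0693), Mcm4 (0.0542) and Dtl (0.060) were not called, nor with offsets for GC content and length Chaf1a (0.0545) and Dtl (0.0679).

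**Figure D4:**
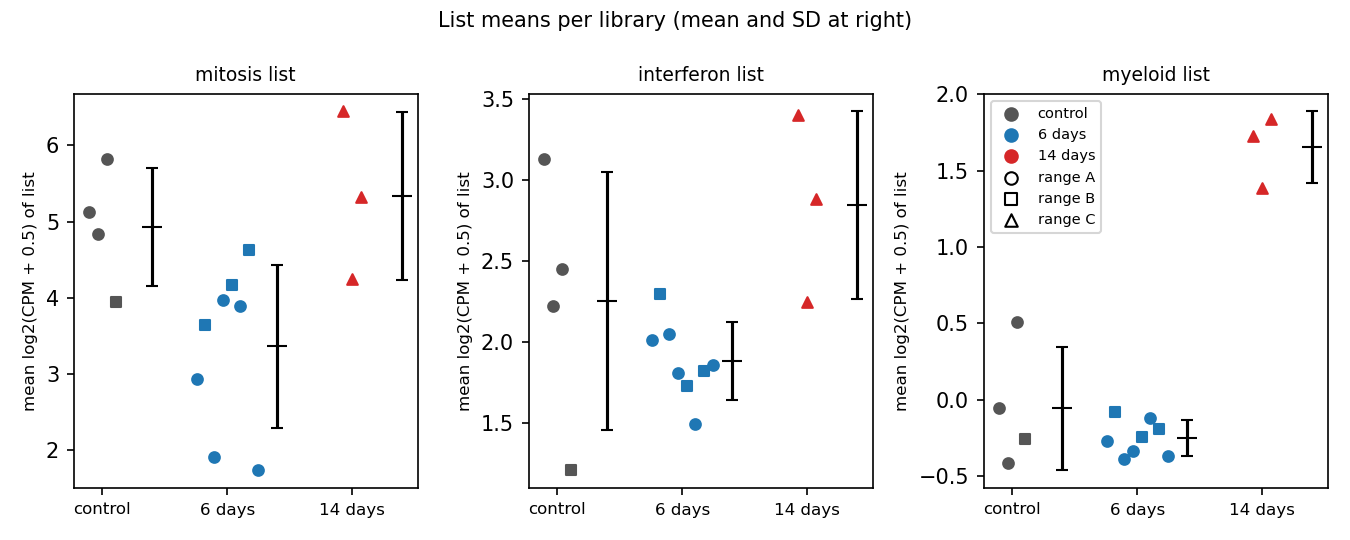
Mean log2(CPM + 0.5) of the mitosis, interferon and myeloid gene lists in each library by group (circle range A, square range B, triangle range C), with the group mean and SD at the right of each group. The mitosis mean averages 4.93 in control, 3.36 at 6 days and 5.34 at 14 days, and the myeloid mean averages -0.06, -0.25 and 1.65.

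Other transcripts higher at 14 than at 6 days included Fcgbp (12.7-fold, 136 ± 61.8 to 1732 ± 2038 CPM), Ankrd35 (6.42-fold), Sema3d (5.77-fold), Krt10 (5.47-fold), the desmosomal cadherin gene Dsg1a (2.86-fold), Tapbp (1.98-fold) and Itga6 (1.49-fold). Without 14-day replicate 1 they were 4.18-fold for Fcgbp, 3.09-fold for Ankrd35, 3.38-fold for Sema3d, 2.33-fold for Krt10 and 1.69-fold for Dsg1a, and Itga6 was not called with offsets for GC content and length (0.0772). In 14-day replicate 2 Krt10 (167 CPM) and Dsg1a (169 CPM) lay within the 6-day libraries. The interferon list rose, with positive fold changes in 18 of 18 members (median 1.25, camera adjusted p = 1.68e-06, and adjusted p = 0.633 with an estimated correlation), with 2 passing, Ifi44 among them, and 8 when adjusted over the list alone. The antigen presentation list rose, with positive fold changes in 14 of 14 members (0.76, 1.94e-05, and adjusted p = 0.633 with an estimated correlation), with 1 passing and 6 when adjusted over the list alone. Differentiation transcripts rose (1.64, 0.00362, and adjusted p = 0.633 with an estimated correlation), 2 of 20 passing and 7 higher and 1 lower when adjusted over the list alone. That call was lost without 14-day replicate 1 (0.360) and with range B as a covariate (0.0544). Myeloid transcripts rose again (median 3.90, or 3.62 with Adgre1 at its bound, camera adjusted p = 5.42e-10, and adjusted p = 0.0261 with an estimated correlation), 5 of 12 passing and 9 when adjusted over the list alone. Adgre1, the macrophage marker F4/80, was at 0 in all 8 6-day libraries and at least 8.06-fold higher at 14 days, taking the highest floor of a single library for the 6-day group. Csf1r was at 8.85 to 15 CPM at 14 days and at most 7.50 CPM in any other library.

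Lower at 14 than at 6 days were Shank1 (9-fold, 38.7 ± 18.0 to 4.30 ± 3.18 CPM), the hair keratin-associated gene Krtap17-1 (7.72-fold), Samd1 (7.51-fold), the hair shaft regulator Hoxc13 (7.30-fold), the ribosomal protein retrogene Rpl37rt (6.83-fold) and the ATP synthase subunit gene Atp5k (6.36-fold). Without 14-day replicate 2 Shank1 was 14.4-fold and Krtap17-1 13.8-fold lower. The pooled 6-day means mix unlike levels. Rpl37rt was at 11.93 to 17.31 CPM in range A, 48.15 to 56.2 CPM in range B and 3.229 to 4.765 CPM at 14 days. Samd1 was at 17.13 to 37.9, 67.49 to 101.1 and 5.246 to 6.581 CPM, and Atp5k at 10.73 to 16.98, 29.29 to 41.71 and 3.314 to 3.593 CPM. Shank1 and Hoxc13 were also higher in every range B than in every range A 6-day library, whereas Krtap17-1 was not. Reads of Rpl37rt and its parent gene, or among keratin-associated genes, can be split between near-identical copies, so those values are uncertain. The 328 lower genes had a median transcript length of 749 and GC content of 52.9%, against 1418 and 50.9% for all tested genes. Immediate early transcripts fell (median -0.69, camera adjusted p = 0.00135, and adjusted p = 0.633 with an estimated correlation), 1 of 15 passing, Zfp36 (2.63-fold lower), and 4 when adjusted over the list alone. Mitochondrially encoded transcripts fell as a list (-2.18, 0.00216, and adjusted p = 0.633 with an estimated correlation), 0 of 9 passing and 4 when adjusted over the list alone. That call was lost with range B as a covariate (0.0628) and without the range B libraries (0.0537). The scarcely counted ATP6, COX2 and COX3 had log2 fold changes of -3.16, -4.15 and -3.11, and the other members ran from -1.13 to -2.68.

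In all, 730 of 18751 genes differed between 14 and 6 days, 402 higher and 328 lower, and 204 and 212 of these by at least 2-fold (edgeR, Benjamini-Hochberg adjusted). Groups were separated in 2194 genes (11.7%, against 1.21% by chance), 629 of them called. The count was 3 without 14-day replicate 1 and 43 without 14-day replicate 3, which ended 38 and 37 of the 38 calls of named genes. It was 485, 363, 446, 468, 277, 411 and 455 without 6-day replicates 1, 2, 3, 4, 5, 7 and 8, and 1138 without control 4. Against the 5 range A 6-day libraries 1187 genes were called and against the 3 of range B 8134, all of these setting range C against another range.

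Of the 91 genes higher at 6 days, 73 were higher at 14 days (3.0 for independent lists), and of the 145 lower, 101 were lower (4.9 for independent lists). None moved in opposite directions, and 235 of the 236 6-day calls had the same sign at 14 days. Both comparisons use the same 4 controls, which alone makes their fold changes agree. Unchanged groups were simulated by drawing every library, controls included, from the control means. They gave 0.1 calls at 6 days and 0 at 14 days, so their 0 shared calls set no chance level. With as many genes taken by lowest p, they shared 69.9 higher (at most 79) and 34.1 lower (at most 46) on average, 0.55 were opposite, and 222.3 of 236 had the same sign (at most 228). By rank, the shared rises thus did not exceed this level, whereas the shared falls did. The simulated genes taken by rank were almost all uncalled, so the level does not say how many called genes unchanged groups would share. Genes were drawn independently and without identifier ranges, so the level leaves out what these add. The excess of shared falls therefore cannot be credited to treatment. Log2 fold changes correlated at r = 0.572 across genes, where the simulated groups gave 0.543 on average and at most 0.567. The covariance was 0.6468, against 0.300 when simulated, a difference of 0.3468. With the controls divided, a pair for each time, the covariance spanned -0.0843 to 0.5977 and r -0.035 to 0.349 over the 6 assignments. Shared calls then numbered 0 to 12 higher and 3 to 37 lower, at lower counts of calls in each comparison, and 13 of 14, 12 of 15, 4 of 4, 101 of 109, 88 of 93 and 63 of 67 6-day calls had the same sign at 14 days.

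Markers of other cell types were measured in the same libraries. Fibroblast, endothelial, pericyte and muscle, Langerhans and red cell lists passed at neither time against control in the pooled fit. The pericyte and muscle list was called lower at 6 days with the range as a covariate (camera adjusted p = 0.0323), with medians of -1.66 in range A and 0.35 in range B. It was also called lower without the range B libraries (0.00136), as was the fibroblast list (0.0157). Pooled medians were -0.82, -0.60, -0.92, -0.47 and -1.16 at 6 days (camera adjusted p = 0.116, 0.308, 0.0675, 0.281 and 0.448). At 14 days they were -1.38, -0.74, -1.59, -0.81 and -1.67 (0.215, 0.404, 0.207, 0.248 and 0.5). Between 14 and 6 days they were -0.55, 0.26, -0.51, -0.36 and -0.51 (0.805, 0.867, 0.773, 0.518 and 0.825). The endothelial gene Egfl7 fell 2.64-fold at 14 days (5.75 ± 1.83 to 2.17 ± 0.362 CPM, adjusted p = 0.0277) and Cd1d1, of the Langerhans list, 2.40-fold (0.0417). Egfl7 kept its call in 10 of 15 left-out fits and Cd1d1 in 5. The Langerhans list had only 4 tested genes, among them Epcam at 616 CPM in control and Cd207 at 1.09 CPM. It is thus a weak measure of Langerhans cells. By exact permutation of list means, 6 of the tests of other cell types had an unadjusted p under 0.05. The exact p was 0.0286, the smallest possible there, for fibroblasts at 14 days (difference -0.56 log2). The others were endothelium at 6 and 14 days (-0.32 each, 0.0404 and 0.0286), myeloid at 14 days (1.71, 0.0286) and against 6 days (1.90, 0.00606) and mitochondrial transcripts against 6 days (-1.18, 0.0485). None passed after adjustment (lowest 0.145). With these numbers of libraries a single list could not pass in either 14-day comparison, so this says nothing against the myeloid rise. Melanocyte gene levels varied widely, the melanocyte and Schwann list mean spanning 1.67 to 5.01 (log2) over the libraries and Dct averaging 146 ± 136 CPM in control and 162 ± 131 CPM at 6 days, with a log2 fold change of -0.25 at 14 days (adjusted p = 0.915). The melanocyte and Schwann list gave medians of -0.01, -0.88 and -0.75 at 6 days, 14 days and between them (adjusted p = 0.899, 0.379 and 0.279). Myeloid transcripts at 6 days gave a median of -0.33 (-0.27 with Adgre1 at its bound, adjusted p = 0.655), and mitochondrial ones 0.25 (0.938). Cd14 averaged 2.91, 3.67 and 4.51 CPM in control, at 6 days and at 14 days (log2 fold change 0.63 at 14 days, adjusted p = 0.293) and Cd68 4.94, 4.41 and 4.37 CPM, and for both another library lay above all 14-day libraries (5.43 and 8.55 CPM). Of the lymphoid list, Cd79a alone was expressed enough to test, at 0.170 ± 0.0775 CPM at 14 days and 0.282 ± 0.228 CPM in control (adjusted p = 0.679).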

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

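All tests of the 3 patterns weighed here were chosen after the results were seen, whereas the counts of other splits were planned. A library is listed where its gap to the next one exceeds Dixon's 95% critical value for its group, of controls or 6-day libraries. The 3 14-day libraries were too few for this and were not examined. Chance gives about 1 in 20, or 12.2 of the 244 groups of values examined, and 20 were found.

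Among controls, replicate 1 was high for C1qb (0.136 CPM, others 0), Ifi44 (0.84 CPM, others 0) and Krt10 (447 CPM, others 163 to 178). Replicate 2 was high for Lef1 (23.3 CPM, others 8.62 to 10.1) and Adgre1 (0.0297 CPM, others 0), and replicate 3 for C1qc (0.469 CPM, others 0 to 0.0271) and the Langerhans list mean (3.91, others 3 to 3.09). Replicate 4, the range B control, was low for Mcm2 (27.9 CPM, others 110 to 138), Mcm4 (35.1 CPM, others 105 to 127), Dtl (5.49 CPM, others 32.9 to 40.7) and the DNA replication list mean (3.75, others 5.43 to 5.50). It was high for Itgam (0.0224 CPM, others 0) and the Notch list mean (5.76, others 4.63 to 4.75). Where the other controls were all at 0, as for C1qb, Ifi44, Adgre1 and Itgam, any count at all is listed. The Adgre1 and Itgam values lay under the floors of their libraries (0.0891 and 0.0336 CPM). At 6 days, replicate 7 was high for Edar (5.40 CPM, others 0.459 to 1.66), Pla2g4f (10.8 CPM, others 0.887 to 3.17) and Fndc1 (27.3 CPM, others 0.918 to 4.69), and replicate 2 for Tgfbi (354 CPM, others 225 to 279). Low values were Smo in replicate 6 (121 CPM, others 213 to 271), Bmp4 in replicate 3 (0 CPM, others 0.689 to 1.56) and the sebocyte list mean in replicate 1 (3.01, others 3.42 to 3.79).

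The effects at 14 and at 6 days differed by the direct test in 730 genes. List medians differed for mitosis (1.86), DNA replication (1.07), differentiation (1.64), interferon (1.25), antigen presentation (0.76), myeloid (3.90), immediate early (-0.69) and mitochondrial transcripts (-2.18). With an estimated correlation only the myeloid call held (camera adjusted p = 0.0261, and 0.441 to 0.633 for the rest). The differentiation (0.0544) and mitochondrial (0.0628) calls were also lost with range B as a covariate. Named genes changed at one time or both and higher at 14 days were, on the log2 scale, Gdpd2 (5.20), Pla2g4f (3.89), Fcgbp (3.67), Il33 (3.26), Ankrd35 (2.68), Sema3d (2.53), Krt10 (2.45), Tapbp (0.98), Itga6 (0.57), C1qb (7.40), C1qc (5.70) and Adgre1 (at least 3.01). Without 14-day replicate 1 none of these calls held, and the values were 3.64 for Gdpd2, 2.0 for Pla2g4f, 2.06 for Fcgbp, 2.46 for Il33, 1.63 for Ankrd35, 1.76 for Sema3d and 1.22 for Krt10. Pla2g4f was at 4.61 without 6-day replicate 7 and C1qb at 8.56 without 6-day replicate 5. In 14-day replicate 2 Gdpd2 (2.61 CPM), Pla2g4f (1.34 CPM), Il33 (9.41 CPM) and Krt10 (167 CPM) lay within the 6-day libraries. Lower at 14 days were Samd1 (-2.91), Hoxc13 (-2.87), Rpl37rt (-2.77), Atp5k (-2.67) and Bax (-0.80). For all of these but Bax, every range B 6-day library lay above every range A one, so the pooled values mix unlike levels. None of these lower calls held without 14-day replicate 1 or replicate 3, and Hoxc13 kept its call in 7 of 15 fits. Offsets for GC content and length ended the Bax call (edgeR adjusted p = 0.0963).

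Other splits of the libraries into groups of the same sizes were fitted on the 2 groups compared. For the genes changed at 6 days a chance division is argued against (199 genes, highest other split 15, 1 of 100 splits as large). At 14 days the real split also gave the most (374 genes, highest other 0, 1 of 35). There 1 of 35 is the smallest share possible and all 14-day libraries lie in range C, so neither chance nor range is excluded. Other splits mix treated and control libraries, so they do not show what unchanged groups would give. For 14 against 6 days 2 of 100 splits gave 818 or more genes, and the highest, 6943, set the 3 range B 6-day libraries against the rest, which points to a structure of the samples that follows the ranges. Dividing range A from range B gave 7269 genes, while 100 of the 224 reassignments of treatment within ranges gave at most 0 genes besides the real one, which gave 844. Chance cannot be excluded for the numbers of lists called, since 74 of 100 splits at 6 days (5 lists, highest other 14), 28 of 35 at 14 days (7 lists, 14) and 34 of 100 between them (10 lists, 15) gave as many.

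Mitosis transcripts were lower at 6 days in range A (difference of list means -2.37, exact permutation p = 0.0357), while the difference in range B was 0.21. Treatment was permuted within ranges after a common effect had been taken off. The exact p for the difference of 2.58 ran from 0.00893 to 0.134 over the effects tried, so spread between libraries stays open. A difference in total count is argued against, since the range B median was 0.25 after thinning to the lowest total, with -2.24 in range A. The lone range B control, at a list mean of 3.94 against 4.84 to 5.82, may be unusual, and with no other range B control this stays open. The difference between the within-range effects was tested as above, but whether it came from the mice of the ranges was not tested.

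Transcripts lower at 14 than at 6 days were short, with a median length of 749 against 1418. After offsets for GC content and length 72.6% of the lower calls remained, with a median of -1.04 in place of -1.16, so a bias of that kind could account for part and stays open. After thinning to the lowest total count 85.7% remained, which argues against total count, the 1 measure of depth that was matched. Range C cannot be told apart from 14 days, as 0 14-day libraries lie outside it. An effect of treatment time stays open and untested.

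Macrophage transcripts appeared in the 14-day libraries, where 7 of the 13 listed myeloid genes were higher in each than in every other library. Macrophages among the sorted cells may account for this, but Cd14 (log2 fold change 0.63) and Cd68 (-0.18) did not pass, and for each another library lay above all 14-day ones, so it stays open, and the gate that would remove them is not given. Depth in total count is argued against by a list median of 4.49 against the deep range B 6-day libraries. A difference between ranges cannot be told apart, with 0 14-day libraries outside range C. Tumour cells expressing these genes were not tested.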

How the results depend on the processing

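The range B covariate, sex, left-out range B, offset and thinning fits were chosen after seeing the data. No paired analysis was possible because replicate numbers were given in accession order only. The pseudocount for normalized values was not run because counts were used. Called genes, given for 6 days, 14 days and 14 against 6 days, numbered 236, 1238 and 730. They were 846, 2752 and 2585 with DESeq2, 826, 4205 and 4693 with limma-voom and sample weights, and 34, 250 and 23 with glmTreat against a fold of 1.5. With range B as covariate they were 866, 3196 and 2036, with sex and range B 798, 2541 and 1434, and without the range B libraries 465, 2330 and 1322. No filter gave 460 for 14 against 6 days, and fitting the 2 groups alone gave 374 at 14 days, with fewer samples behind the spread. The range as covariate gave 844 and range A alone 468 at 6 days. Against range B 6-day libraries 14 days gave 8134 and against range A 1187. RLE, upper-quartile, GC and length, thinning, 10 CPM and range A control settings stayed within 1.5 times. For the rest, the cause was not tested.

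Leaving out each library gave 69 to 308, 376 to 1438 and 3 to 1138 genes, 18 to 29 lists and 33 to 113 calls of named genes (main 22 and 111). Lists called fell to 3 with an estimated correlation and 7 with fry. Shared calls fell from 174 to 10, 8, 3, 39, 45 and 30 with divided controls, where each comparison has fewer samples. Cholesterol synthesis at 6 days was called lower without range B libraries (adjusted p = 0.0394, range over its alternatives 0.0394 to 0.928), and was not called otherwise. Over settings other than single left-out libraries, named genes stayed on the same side of the threshold in 1315 cases, gained a call in 80 and lost one in 40, and lists in 411, 8 and 45. With single libraries left out these were 3823, 26 and 468 for genes and 1107, 41 and 19 for lists. Results uncalled both ways were counted as unchanged whatever their sign, and some changed sign, such as Ly6a at 6 days (log2 fold change -1.71 to 2.8). Depth limits transcripts under 0.105 CPM in the shallowest library.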

Other observations

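Further lists fixed before the data were examined passed in no comparison, though single members did. Among p53 readouts, in tumours built on conditional Trp53 alleles, the apoptosis genes Bbc3 (3.18-fold, 24.2 ± 8.28 to 7.62 ± 1.02 CPM, n = 4 and 3, adjusted p = 0.00647) and Bax (1.92-fold, adjusted p = 0.0134) fell at 14 days. The list medians were -0.08, -0.34 and -0.23 for 6 days, 14 days and 14 against 6 days (camera adjusted p = 0.379, 0.229 and 0.441). Bbc3 kept its call in 15 of 15 left-out fits, while Bax lost it without 14-day replicate 1 or 3 (highest adjusted p = 0.0781). The Bbc3 call was lost when the 2 groups alone were fitted (edgeR adjusted p = 0.0516). Notch genes gave medians of -0.21, -0.42 and -0.27 (0.229, 0.253 and 0.566), with Heyl lower at both times and Nrarp, a Notch feedback gene, 1.88-fold lower at 14 days (184 ± 36.1 to 97.9 ± 28.0 CPM, adjusted p = 0.0409, kept in 4 of 15 fits). Of 11 BMP and TGF-beta transcripts 8 did not pass between 14 and 6 days. The ligand gene Bmp4 (0.828 ± 0.443 to 13.9 ± 16.6 CPM, adjusted p = 0.0293) and Tgfbi (1.83-fold, 0.0454) were higher and the BMP antagonist gene Nog (3.59-fold, 0.0287) lower. None of these 3 calls held without 14-day replicate 1 or 3 (highest 0.410, 0.470 and 0.247), and without replicate 1 Bmp4 was 5.48-fold higher in place of 16.7-fold. In 14-day replicate 2 Bmp4 was at 0.706 CPM, under the 6-day mean. The list medians were -0.04, -0.22 and -0.38 (0.379, 0.883 and 0.377).

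Hair germ and placode genes gave medians of -0.19, -0.11 and -0.33 (camera adjusted p = 0.899, 0.571 and 0.379), while their members Edar and Sox4 fell and Ccn2 rose. Sebocyte genes gave -0.08, 0.25 and 0.39 (0.805, 0.379 and 0.204), wound keratinocyte genes 0.26, 0.73 and 0.33 (0.162, 0.404 and 0.979) and cholesterol synthesis genes 0.17, 0.11 and 0.12 (0.562, 0.594 and 0.867). In the comparisons not described elsewhere, medians were 0.32 and 0.36 for basal epidermis at 6 days and 14 against 6 days (0.124 and 0.0589, the latter 0.00141 with range B as a covariate), 0.18 for differentiation at 6 days (0.248), and -0.38 and 0.61 for the upper follicle (0.470 and 0.0546, the latter 0.0408 with offsets for GC content and length). They were -0.66 for interferon (0.0505, and 0.000166 without the range B libraries) and 0.13 for antigen presentation (0.805) at 6 days, -0.38 for immediate early genes at 14 days (0.229), and -0.26, -0.24 and -0.63 for bulge, Wnt and Hedgehog genes between 14 and 6 days (0.124, 0.979 and 0.248). Mitosis and DNA replication at 14 days gave 0.49 and 0.42. The median, the mean and the test differed in sign for upper follicle, antigen presentation, melanocyte, hair germ and BMP lists at 6 days, and for wound, Wnt, endothelial and cholesterol lists between 14 and 6 days.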
